A study of Mus musculus with 23 samples.

How the data were processed

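RNA was isolated by the authors from whole proximal small intestine, and libraries were made from poly-A selected mRNA and sequenced as 150-base read pairs, per the labels. The submitters' processing notes name Trim Galore, STAR, DESeq2 and the mouse genome build mm10, without versions. The deposited table holds 16259 genes in 23 libraries as signal values, which are read counts divided by 1 factor per library, not log transformed. How reads were assigned to genes, the annotation and any filter on genes are not stated.

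Each library's values were whole multiples of 1 step, so reads were recovered by dividing by that step, and 100% of values lay within 0.01 of a whole read (largest deviation 6.82e-05 of a read). Recovered reads per library, in units of 1e+06, ranged from 11.42 to 23.43 (median 15.52), genes with a read from 12360 to 14480, and the 10 largest genes held 8.79% to 12.1% of the values. Size factors lay between 0.598 and 1.42, so 1 read stood for 0.705 to 1.67 normalized reads, which sets the smallest step that a value can resolve. No 2 libraries were copies of each other (253 pairs, Pearson r from 0.885 to 0.975). The first 4 principal components held 18.3%, 11.8%, 8.53% and 7.18% of the variance.

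Values were analysed as log2(value + 1) for the 11939 genes with a mean of at least 10 normalized reads over all libraries, and 49 genes were at 0 everywhere. Folds are on this log2(value + 1) scale, and an error after a log2 value is its standard error. Every library was its own condition and genotype, so a linear model had 12 conditions plus genotype over all 23 libraries, with 10 residual degrees of freedom, and the wild-type and knockout libraries of a condition stood in for replicates. The residual spread therefore includes any genotype effect that differs between conditions, and p-values measure only the spread between these libraries. Feeding before doxorubicin was tested in 14 libraries that form 7 pairs matched on genotype and time (6 residual degrees of freedom; 5 for the tests by genotype and by time), and the difference in knockout effect between drug groups with a genotype by drug term (9 residual degrees of freedom).

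Tests were two-sided with limma 3.58.1 (eBayes with a trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each comparison, and the prefast effect at 6, 12 and 24 h alone, was also run with edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. The tests, 52 gene lists and the rule for naming genes were fixed before the data were examined, and 50 lists had enough genes to test. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, with adjustment over the lists of a comparison. Members were counted as passing over all genes and adjusted over the list alone. The rule named Ddit4, the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 50 and 1 direction in every matched pair (4 and 4 for tests of a difference), the 3 members with the smallest p of up to 8 passing lists, and a fixed set of marker genes; unnamed gene models and immune receptor segments were passed over. Some genes are not reported here. The text gives a selection of the genes so named and says where a gene was named after its values were seen.

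Tested on simulated data of the same size, with 100 genes changed 2-fold and 100 changed 4-fold, limma recovered 97% and 100% for the genotype comparison (10 false calls), 91% and 99% for the feeding pairs (8 false calls), and 33% and 94% for the 12 h doxorubicin contrast (10 false calls). For that last contrast edgeR recovered 35% and 91% with 6 false calls, and DESeq2 44% and 95% with 32 false calls. The changed genes were drawn from those with a mean of at least 50 normalized reads. Each gene's spread was set by its expression level alone, and its change was the same in every library of the group. Differences in tissue content or in response between times were not simulated, so recovery in the real libraries may be lower.

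Alternatives covered the pseudocount, the filter on low values, quantile normalization, rescaling to the same median ratio, array weights, edgeR, DESeq2, subsets of pairs, the 4 libraries with conflicting titles and each library left out in turn. When a library is left out, its condition keeps 1 library, which is assumed to vary like the others. Leaving out the 3 libraries that lack Y-linked reads (fewer than 20 such reads), leaving out the 2 with pancreatic transcripts and adding the Paneth marker level as a covariate were chosen after seeing the data. Rescaling moved the share of risen genes among changed genes by less than 10 percentage points in every comparison, the most from 65.9% to 57.4% (fasted, quantile normalization). Gene positions were taken from the GENCODE annotation of mm10.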

Results

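Poly-A selected RNA from whole proximal small intestine of mice, all labelled male, was sequenced in 23 libraries, 12 from wild-type mice and 11 from Ddit4 knockout mice. Ddit4 encodes an inhibitor of mTORC1 that stress and fasting induce. Mice were fed ad libitum (9 libraries), fasted for 24 h (2 libraries) or fasted and then refed (12 libraries, called prefasted here). Of these, 15 libraries came from mice given doxorubicin, a DNA-damaging chemotherapy, at 20 mg/kg by intraperitoneal injection 2, 6, 12 or 24 h before harvest, and 8 came from untreated mice at 0, 2 or 6 h. Each combination of feeding, drug, time and genotype had 1 library, so no condition had replicates of its own genotype. There were 12 conditions, 11 of which had both genotypes, and the knockout library fed ad libitum 2 h after doxorubicin was not analysed here. The reads in genes, in units of 1e+06, ranged from 11.42 to 23.43 per library, and 1 read corresponded to a value of 0.705 to 1.67 normalized reads.

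The first comparison checked the targeted gene itself. Ddit4 (mm10, chromosome 10, 59949669 to 59951834, 3 exons) had 278 ± 106 normalized reads in wild-type libraries (SD, n = 12) and 1.83 ± 3.49 in knockout libraries (SD, n = 11). It was lower in the knockout library of 11 of 11 pairs, with a log2 difference of -7.09 ± 0.42 (SE) and an adjusted p of 1.3e-07. Of the knockout libraries, 7 had 0 reads of Ddit4 and the most had 16, against 48 to 399 in the wild type. Among single wild-type libraries, Ddit4 stood without drug at 180.4 normalized reads in the ad libitum mouse, 289 in the fasted mouse, 304 after 2 h of refeeding and 134 after 6 h. After doxorubicin it stood at 337, 296, 230.0 and 414 at 2, 6, 12 and 24 h in ad libitum mice and at 375, 66.9, 379 and 329 in prefasted mice, each from 1 library and untested.

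Other labels were compared with the reads in the same way. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 1088 to 2030 reads in 20 libraries and at most 5 in the other 3, all of them knockout and untreated (ad libitum, fasted, and refed for 2 h), although all 23 are labelled male. In 4 wild-type prefasted libraries (2, 6, 12 and 24 h) the title says untreated while the drug label says doxorubicin, and the drug label was used. The p53 target genes, on average per library and relative to each gene's mean over all libraries, stood at -0.37 ± 0.40 on the log2 scale in untreated libraries (SD, n = 8), 0.22 ± 0.32 in the doxorubicin libraries whose labels agree (n = 11) and 0.15 ± 0.17 in the 4 with the conflicting title. Their ranges overlapped, at -1.26 to 0.03, -0.36 to 0.69 and -0.07 to 0.30 in that order, so this list cannot settle the label of a single library.

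**Figure D1:**
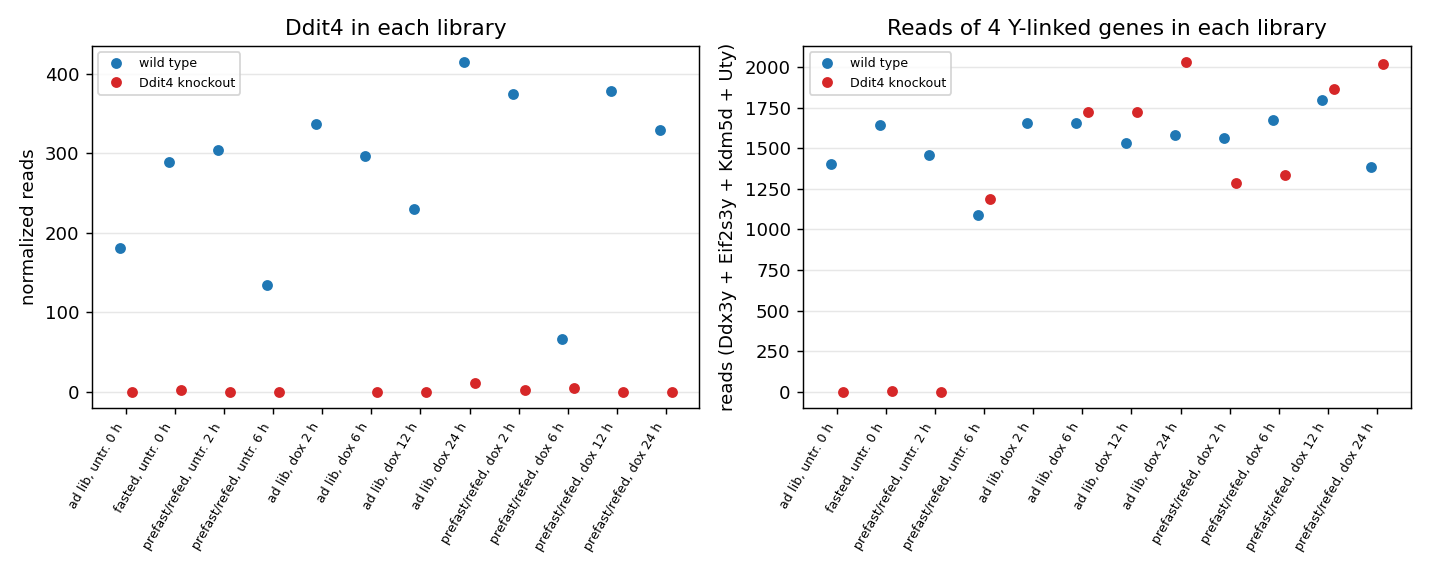
Ddit4 in normalized reads (left) and the summed reads of 4 Y-linked genes (right) in each library, by condition, with 1 point per library coloured by genotype. Ddit4 lay at 66.9 or more in every wild-type library and at 11.3 or less in every knockout library, and 3 untreated knockout libraries had at most 5 Y-linked reads.

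Knockout and wild-type libraries were compared to ask what loss of Ddit4 changed across feeding states and drug. The antigen presentation genes Cd74, H2-Ab1 and H2-DMa of MHC class II were higher in the knockout in every pair. Cd74, the invariant chain that chaperones class II molecules, rose 7.83-fold (log2 2.97 ± 0.30, SE, 11 pairs, adjusted p = 9.3e-05), from 543 to 8030 normalized reads across wild-type libraries to 5840 to 69000 across knockout libraries. H2-Ab1, a class II beta chain, rose by log2 2.20 ± 0.23 (adjusted p = 0.00015), and H2-DMa, which loads peptides onto class II, by 2.27 ± 0.22 (adjusted p = 8e-05). Of the interferon-induced genes, Zbp1, a sensor of unusual nucleic acids, rose by log2 1.10 ± 0.11 (adjusted p = 8e-05), Oas1a by 0.64 ± 0.10 and Oasl2 by 0.57 ± 0.11. The cytotoxic lymphocyte genes Nkg7 (0.86 ± 0.12), Gzmb (0.65 ± 0.12) and Gzma (0.59 ± 0.13) rose, and Mtarc1 and Clk1 fell, by log2 -1.04 ± 0.19 and -0.65 ± 0.11.

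In all, 52 genes rose and 17 fell in the knockout of 11939 tested. Of 9 MHC class II genes, 6 rose over all genes and 7 adjusted over the list alone (camera, adjusted p = 7.3e-19 with the preset correlation, adjusted p = 0.10 with an estimated correlation). Of 27 interferon-stimulated genes, 7 rose over all genes and 15 adjusted over the list alone (camera, adjusted p = 3.4e-20; adjusted p = 0.10 with an estimated correlation). Among 13 T cell markers the counts were 3 and 8 (camera, adjusted p = 5.4e-10; adjusted p = 0.10 with an estimated correlation). The level of the B cell markers was lower in the knockout library in 7 of the 11 pairs, and the level of the T cell markers was higher in 10. Duox2, which makes hydrogen peroxide at the mucosal surface, had a log2 difference of 3.69 ± 0.92 but missed the threshold (adjusted p = 0.09, higher in 10 of 11 pairs). The count was 16 without the 3 libraries that lack Y-linked reads, 20 without the 4 with the conflicting title, 12 in the doxorubicin pairs alone and 1, Ddit4, in the 4 untreated pairs alone. It was 39 without either untreated library refed for 2 h, 45 without the fasted knockout library, 43 without either ad libitum library at 12 h of doxorubicin and 44 without the prefasted knockout library at 12 h.

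**Figure D2:**
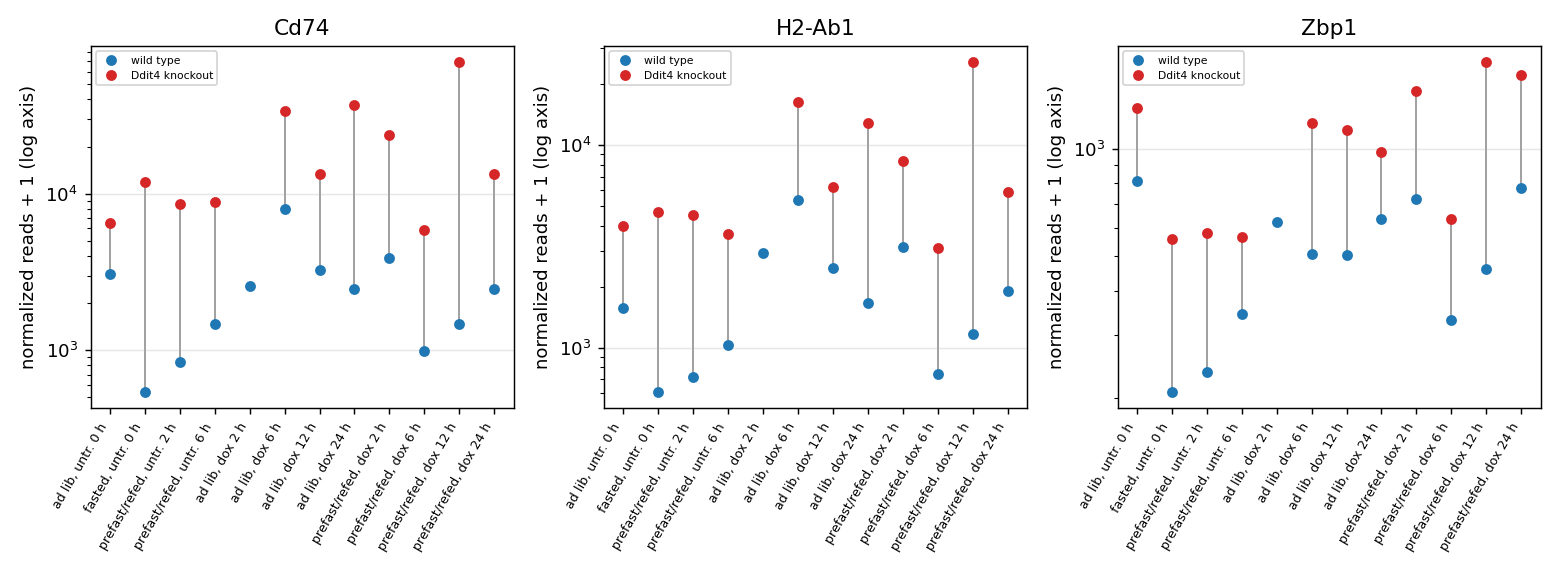
Normalized reads plus 1 (log axis) of Cd74, H2-Ab1 and Zbp1 in each library by condition, with lines joining the wild-type and knockout library of a condition. Each gene was higher in the knockout in all 11 pairs, and Cd74 spanned 543 to 8030 in the wild type and 5840 to 69000 in the knockout.

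Whether doxorubicin altered the knockout effect was tested as the difference between 7 doxorubicin pairs and 4 untreated pairs. No gene passed in limma (0 genes, with 497 at an unadjusted p under 0.05 where chance gives 597), 0 passed in edgeR and 7 in DESeq2. Without the 3 libraries lacking Y-linked reads, the only untreated pair left is that refed for 6 h, whose wild-type library holds pancreatic transcripts. That setting therefore cannot test the difference. Without either untreated library refed for 6 h the count was 4, namely Ddx3y, Eif2s3y, Kdm5d and Uty, and without either prefasted library at 2 h of doxorubicin it was 1, Osr2, all named after their values were seen. The untreated knockout libraries left in the former setting all lack Y-linked reads, while every doxorubicin knockout library has them. The 4 Y-linked calls follow from that, and whatever sets those 3 libraries apart is mixed with drug within the knockout.

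Fasted and ad libitum untreated libraries were compared to describe the fasting response itself. Fkbp5, a glucocorticoid-induced chaperone, rose 22.5-fold from 106 ± 15.7 to 2400 ± 288 normalized reads (SD, n = 2 per condition; log2 4.49 ± 0.88, adjusted p = 0.036). The aldose reductase relative Akr1b7 rose from 1410 ± 220 to 13200 ± 1710 (log2 3.23 ± 0.37, adjusted p = 0.0014), the translation inhibitor Eif4ebp3 by log2 4.91 ± 0.70 and the drug-metabolizing enzyme Cyp3a11 by 2.42 ± 0.40. Cyp51, an enzyme of cholesterol synthesis, fell by 1.77 ± 0.36 on the log2 scale, and the small proline-rich protein gene Sprr2a3 by 3.41 ± 0.46. Pdk4, which spares glucose by blocking pyruvate oxidation, had a log2 change of 2.55 ± 0.68 and missed the threshold (adjusted p = 0.18).

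Over all genes 27 rose and 14 fell with fasting. The PPAR-alpha and fat oxidation list (25 genes) had 1 risen gene over all genes and 7 adjusted over the list alone (camera, adjusted p = 3.1e-11; adjusted p = 0.084 with an estimated correlation). Glucocorticoid-responsive genes counted 1 of 14 over all genes and 6 adjusted over the list alone (camera, adjusted p = 4.4e-05; adjusted p = 0.25 with an estimated correlation). Of 24 cholesterol synthesis genes, 1 fell over all genes and 2 adjusted over the list alone (camera, adjusted p = 1.9e-06; adjusted p = 0.25 with an estimated correlation). Tissue content differed too, since the fasted knockout library stood at 7.71 on the log2 scale for pancreatic acinar markers and at 3.94 for B cell markers, relative to the mean of all libraries. Leaving out 1 library gave 16 changed genes (wild-type ad libitum), 3 (wild-type fasted: Akr1b7, Eif4ebp3 and Ptgr1), 5 (knockout ad libitum: Akr1b7, Apol10a, Mtarc1, Ptgr1 and Sult1d1) and 7 (knockout fasted). The count was 0 without the 3 libraries lacking Y-linked reads, 2 of which are in this contrast, and 12 without the 2 libraries with pancreatic transcripts.

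Refeeding for 2 h was compared with fasting to describe the early return of food. Hsph1, an HSP110 family chaperone, rose 13.2-fold from 299 ± 0.518 to 4120 ± 1630 normalized reads (SD, n = 2 per condition; log2 3.72 ± 0.37, adjusted p = 0.00028). Hspa1b, an inducible HSP70, rose by log2 5.24 ± 0.78, Hsp90aa1 by 1.84 ± 0.21 and Hyou1, a chaperone of the endoplasmic reticulum, by 1.17 ± 0.16. The choline kinase gene Chka rose by 2.02 ± 0.29, while Pdk4 fell from 6440 ± 608 to 557 ± 37.3 normalized reads (log2 -3.53 ± 0.68, adjusted p = 0.043) and the cold-inducible RNA-binding protein gene Cirbp fell by 1.94 ± 0.32.

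At 2 h of refeeding 17 genes rose and 13 fell. Of 13 heat shock genes, 6 rose over all genes and 10 adjusted over the list alone (camera, adjusted p = 7.1e-21; adjusted p = 0.031 with an estimated correlation). Unfolded protein response genes counted 1 of 19 and 10 adjusted over the list alone (camera, adjusted p = 9.4e-12; adjusted p = 0.048 with an estimated correlation). Of 24 cholesterol synthesis genes, 1 rose over all genes and 9 adjusted over the list alone (camera, adjusted p = 1.5e-07; adjusted p = 0.13 with an estimated correlation). Among 16 FOXO and insulin-responsive genes, 1 fell over all genes and 5 adjusted over the list alone (camera, adjusted p = 0.00024; adjusted p = 0.048 with an estimated correlation). The 9 fat tissue markers had 0 risen over all genes and 8 adjusted over the list alone (camera, adjusted p = 1.5e-11; adjusted p = 0.048 with an estimated correlation), and in the untreated libraries refed for 2 h they stood at 3.31 (knockout) and 2.30 (wild type) on the log2 scale relative to the mean of all libraries. Paneth cell markers stood at 2.46 (wild type) and 1.48 (knockout) in the same libraries.

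The count at 2 h was 4 without the wild-type fasted library (Hsp90aa1, Hspa1b, Hsph1 and Srsf5) and 3 without its knockout partner (Fabp4, Hsp90aa1 and Hsph1). It was 6 without either library refed for 2 h, 19 without either ad libitum library at 6 h of doxorubicin, and 17 and 16 without the wild-type or knockout one at 12 h. Without the 3 libraries lacking Y-linked reads it was 2 (Hsp90aa1 and Hsph1), and without the 2 with pancreatic transcripts 3 (Fabp4, Hsp90aa1 and Hsph1).

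Refeeding for 6 h was compared with the same fasted libraries. Insig1, a sterol sensor, rose by log2 2.89 ± 0.47 (SE, n = 2 libraries per condition, adjusted p = 0.0062), from 834 ± 218 to 6260 ± 2210 normalized reads (SD). Slc2a5, the fructose transporter, rose by 2.01 ± 0.35 (adjusted p = 0.0072). Pck1, the gluconeogenic enzyme, fell from 27500 ± 7680 to 1070 ± 305 normalized reads (SD, n = 2; log2 -4.68 ± 1.03), and Fkbp5 fell by 3.56 ± 0.88 on the log2 scale. Genes that fell also included the stem cell marker Olfm4 (log2 -2.23 ± 0.63), the topoisomerase Top2a (-1.82 ± 0.53) and the replication licensing gene Mcm5 (-2.77 ± 0.70).

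In this contrast 425 genes rose and 413 fell. Of 24 cholesterol synthesis genes, 8 rose over all genes and 13 adjusted over the list alone (camera, adjusted p = 3.6e-07; adjusted p = 0.49 with an estimated correlation). Of 37 cytosolic ribosomal protein genes, 14 fell over all genes and 25 adjusted over the list alone (camera, adjusted p = 1.3e-11; adjusted p = 0.49 with an estimated correlation). G2/M genes counted 2 fallen of 26 over all genes and 11 adjusted over the list alone (camera, adjusted p = 1.4e-06; adjusted p = 0.49 with an estimated correlation). The Paneth cell markers, from cells at the crypt base, had a median log2 change of -1.51, and they stood at -1.93 in the untreated knockout library refed for 6 h. The 4 B cell markers had a median of -2.99, with 0 past the threshold by either count (over all genes or adjusted over the list alone), so tissue content may differ beyond the crypt. Leaving out the fasted knockout library left 1 gene (Ifit2), and leaving out the 3 libraries lacking Y-linked reads, of which it is 1, left 0. Without the 2 libraries with pancreatic transcripts, which are the fasted knockout library and the wild-type library refed for 6 h, 81 genes passed.

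**Figure D3:**
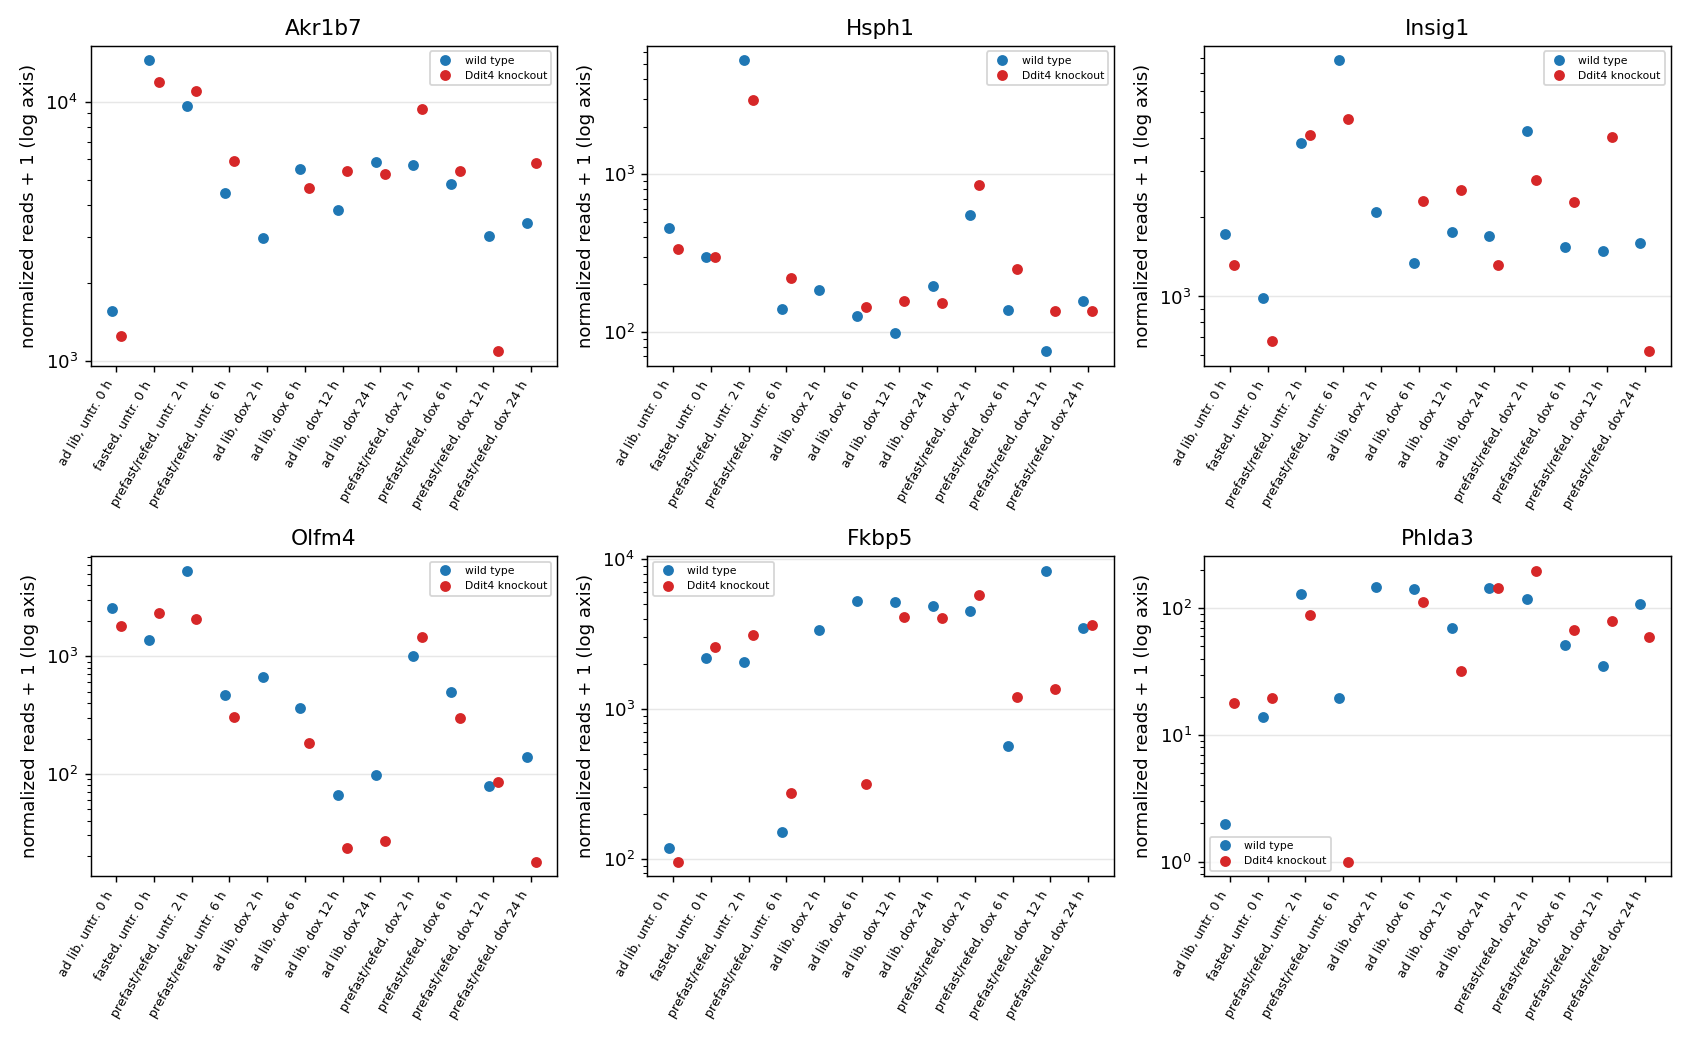
Normalized reads plus 1 (log axis) of Akr1b7, Hsph1, Insig1, Olfm4, Fkbp5 and Phlda3 in each library by condition, with 1 point per library coloured by genotype. Insig1 averaged 834 in fasted libraries and 6260 after 6 h of refeeding without drug, and Olfm4 averaged 2180 in ad libitum untreated libraries and 44.1 at 12 h of doxorubicin.

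Doxorubicin was compared with untreated ad libitum libraries at 6, 12 and 24 h to describe what differed after the drug in ad libitum mice. These 3 contrasts share the same pair of untreated libraries, taken at 0 h, and no untreated ad libitum library matched the later times. Fasting without drug moved some genes named below in the same direction against that pair. Its log2 changes were 4.49 ± 0.88 for Fkbp5, 3.10 ± 0.59 for Slc5a12 and 4.92 ± 1.40 for Zbtb16 (adjusted p = 0.23 for the last). Others moved little with fasting, such as Olfm4 (-0.26 ± 0.63) and Ccng1 (0.19 ± 0.15). At 6 h, the circadian clock gene Per2 was higher by log2 3.53 ± 0.34 (SE, n = 2 per condition, adjusted p = 2e-04), Per3 by 6.59 ± 0.84 and Dbp by 6.56 ± 1.09, and their opposite-phase partner Arntl fell by 2.72 ± 0.44. The dicarboxylate transporter Slc13a2 rose by 4.42 ± 0.46 and the monocarboxylate transporter Slc5a12 by 4.42 ± 0.59. The p53 target Ccng1 rose by 0.88 ± 0.15 (adjusted p = 0.011), from 967 ± 61.1 to 1780 ± 57.4 normalized reads. Olfm4 fell by 3.05 ± 0.63, the log2 change of the crypt transcription factor Myb was -2.95 ± 0.68 and that of the mitotic cyclin Ccnb2 -2.49 ± 0.56.

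At 6 h 108 genes rose and 52 fell. Of 11 clock genes of the Nr1d1 phase, 8 rose over all genes and 10 adjusted over the list alone (camera, adjusted p = 3.8e-16; adjusted p = 0.093 with an estimated correlation). Enterocyte markers counted 2 of 24 and 10 adjusted over the list alone (camera, adjusted p = 9.8e-08; adjusted p = 0.29 with an estimated correlation). The p53 target genes counted 1 of 32 and 4 adjusted over the list alone (camera, adjusted p = 8.2e-05; adjusted p = 0.24 with an estimated correlation). Among 26 G2/M genes 1 fell over all genes and 5 adjusted over the list alone (camera, adjusted p = 1.9e-10; adjusted p = 0.29 with an estimated correlation). Paneth cell markers had a median log2 change of -1.29 beside -1.58 for G2/M genes, so crypt share may differ at 6 h too, while the B cell markers had -0.14. Slc13a2 averaged 660 ± 584 normalized reads in the ad libitum untreated libraries, 3690 ± 48.5 in the fasted and 3200 ± 207 in the untreated ones refed for 6 h, against 11100 ± 1690 at 6 h of doxorubicin. Leaving out 1 library gave 40 genes (wild-type untreated), 6 (knockout untreated), 28 (wild-type at 6 h) and 22 (knockout at 6 h). Without the 3 libraries lacking Y-linked reads the count was 5, namely Per2, Per3, Slc13a2, Slc5a12 and Tef.

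At 12 h of doxorubicin, the stem cell marker Olfm4 fell from 2180 ± 549 to 44.1 ± 30.6 normalized reads (SD, n = 2 per condition; log2 -5.76 ± 0.63, adjusted p = 0.00014), with E2f2, a cell cycle transcription factor, at -3.87 ± 0.43, the Paneth cell lysozyme Lyz1 at -2.72 ± 0.48 and the proliferation antigen Mki67 at -1.94 ± 0.55. Other stem cell markers did not fall as far, and the list of them had a median log2 change of -0.84. Lgr5, with a mean of 16.3 normalized reads over all libraries, was at 0.61 ± 1.17 (adjusted p = 0.80). Fkbp5 rose from 106 ± 15.7 to 4670 ± 755 (log2 5.45 ± 0.88, adjusted p = 0.002). Zbtb16, another glucocorticoid-induced gene, was at 0 in both untreated libraries and at 322 ± 203 here. Per2 rose by 4.46 ± 0.34 (adjusted p = 6.8e-06), the brush border genes Slc6a19 and Mgam by 1.94 ± 0.19 and 1.51 ± 0.28, and the p53 target Cdkn1a, an inhibitor of the cell cycle, from 5030 ± 414 to 8620 ± 1.9 (log2 0.78 ± 0.19, adjusted p = 0.017).

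The 12 h contrast had 571 risen and 503 fallen genes. Of 37 cytosolic ribosomal protein genes, 24 fell over all genes and 28 adjusted over the list alone (camera, adjusted p = 6.9e-18; adjusted p = 0.34 with an estimated correlation), with Rplp0 at log2 -1.46 ± 0.27. G2/M genes counted 7 fallen of 26 and 16 adjusted over the list alone (camera, adjusted p = 5.2e-09; adjusted p = 0.41 with an estimated correlation). Of 24 enterocyte markers, 9 rose over all genes and 14 adjusted over the list alone (camera, adjusted p = 4.5e-09; adjusted p = 0.25 with an estimated correlation). The Nr1d1-phase clock list had 8 risen genes of 11 by either adjustment, over all genes and adjusted over the list alone (camera, adjusted p = 1.2e-08; adjusted p = 0.25 with an estimated correlation). Glucocorticoid-responsive genes counted 5 risen of 14 and 7 adjusted over the list alone (camera, adjusted p = 0.00013; adjusted p = 0.25 with an estimated correlation). For p53 target genes the counts were 3 of 32 and 4 adjusted over the list alone (camera, adjusted p = 0.034; adjusted p = 0.42 with an estimated correlation). Of 17 Paneth cell markers 3 fell over all genes and 10 adjusted over the list alone (camera, adjusted p = 0.00011; adjusted p = 0.48 with an estimated correlation). Of 10 smooth muscle markers 5 and 7 (adjusted over the list alone) fell (camera, adjusted p = 9.5e-05; adjusted p = 0.41 with an estimated correlation). The 4 B cell markers had a median log2 change of -2.20, with 0 past the threshold by either count. Leaving out 1 library gave 338 (wild-type untreated), 210 (knockout untreated), 387 (wild-type at 12 h) and 145 genes (knockout at 12 h). Without the 3 libraries lacking Y-linked reads 102 genes passed.

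At 24 h of doxorubicin, Phlda3, a p53-induced inhibitor of Akt, rose from 8.96 ± 11.3 to 144 ± 0.563 normalized reads (SD, n = 2 per condition; log2 4.60 ± 1.07, adjusted p = 0.03), Ccng1 by 0.90 ± 0.15 and the pro-apoptotic Pmaip1 by 2.16 ± 0.56. Ly6a, a marker of regenerating epithelium, rose by 3.44 ± 0.85 and Reg3b, an antimicrobial lectin, by 3.11 ± 0.74, from 20500 ± 8300 to 171000 ± 34200. The interferon regulatory factor Irf7 rose by 1.02 ± 0.22 and Fkbp5 by 5.38 ± 0.88. Olfm4 was at -5.38 ± 0.63 on the log2 scale (adjusted p = 0.0014), and the respiratory chain gene Uqcrfs1 fell by 1.02 ± 0.18. The stem cell marker list had a median log2 change of -0.41, with Lgr5 at 0.02 ± 1.17.

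Over all genes 207 rose and 164 fell at 24 h. Paneth cell markers had a median log2 change of -1.16 and B cell markers one of -1.85, so tissue content may differ at this time too. Interferon-stimulated genes counted 7 risen of 27 and 15 adjusted over the list alone (camera, adjusted p = 3.4e-08; adjusted p = 0.34 with an estimated correlation). Targets of p53 counted 3 of 32 and 7 adjusted over the list alone (camera, adjusted p = 0.00032; adjusted p = 0.27 with an estimated correlation). Of 32 nuclear genes of oxidative phosphorylation, 7 fell over all genes and 23 adjusted over the list alone (camera, adjusted p = 7.4e-17; adjusted p = 0.34 with an estimated correlation). Antimicrobial and IL-22-responsive genes, a list that holds Reg3b, had 1 risen and 2 fallen of 13 by both counts, over all genes and adjusted over the list alone (camera, adjusted p = 0.31; adjusted p = 0.61 with an estimated correlation). The Nr1d1-phase clock genes were 5 of 11 and 7 adjusted over the list alone (camera, adjusted p = 3.4e-08; adjusted p = 0.27 with an estimated correlation). Leaving out 1 library gave 135 genes (wild-type untreated), 40 (knockout untreated), 164 (wild-type at 24 h) and 8 (knockout at 24 h), and 17 passed without the 3 libraries lacking Y-linked reads.

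**Figure D4:**
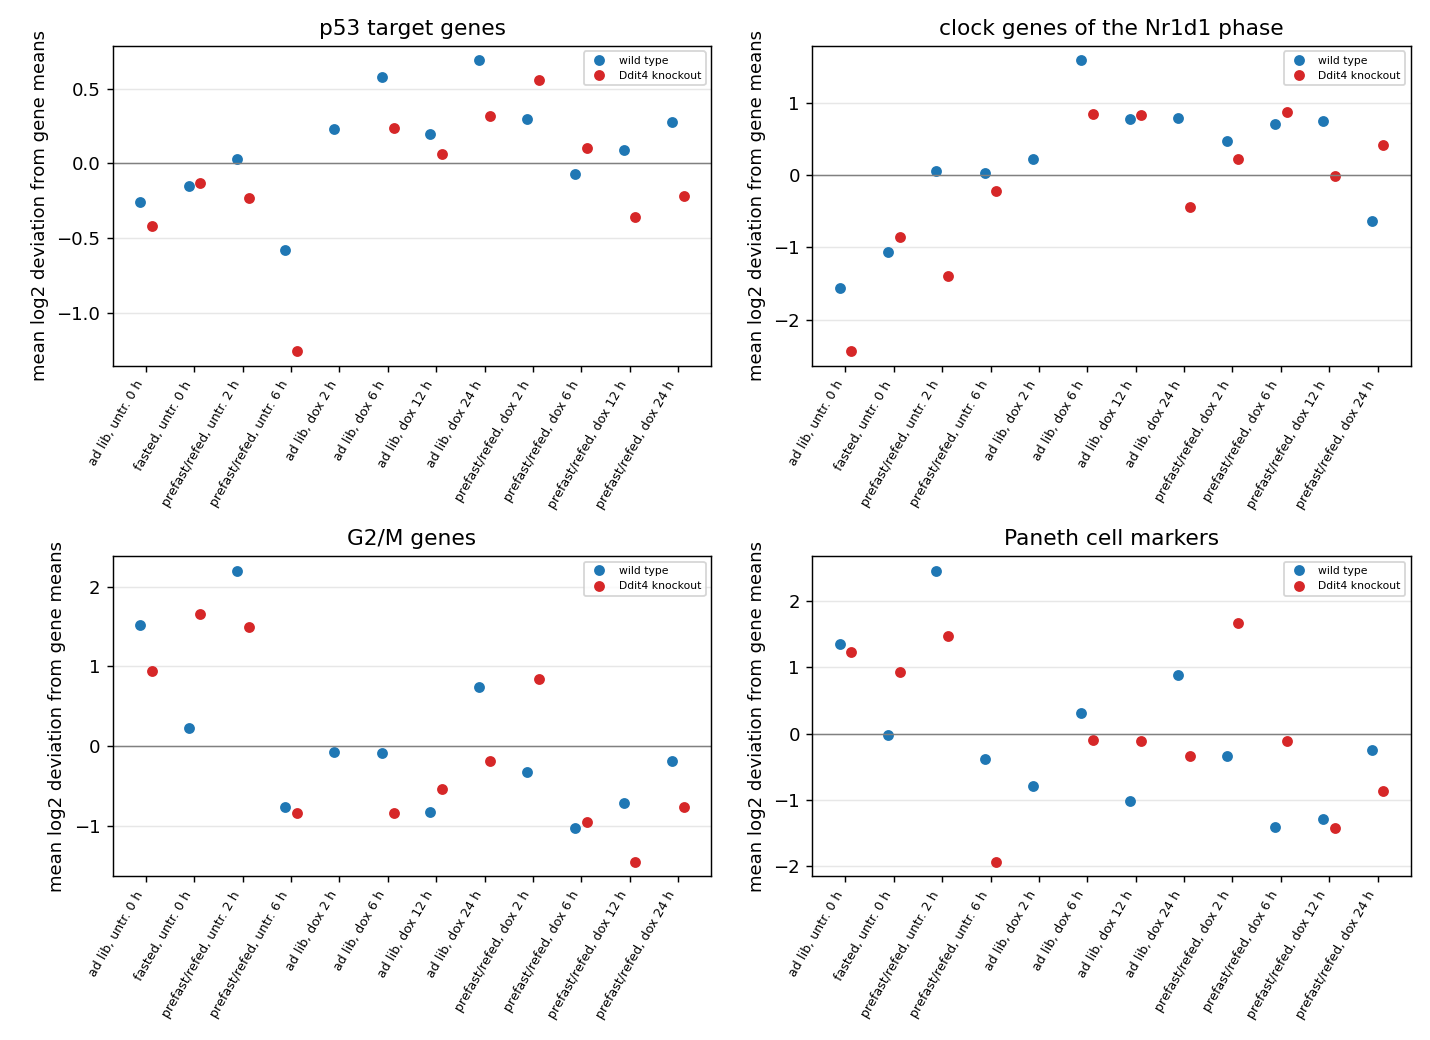
Mean log2 deviation from each gene's mean over all libraries, per library, for p53 target genes, clock genes of the Nr1d1 phase, G2/M genes and Paneth cell markers, by condition and coloured by genotype. The clock genes were lowest in the ad libitum untreated libraries, at -1.56 (wild type) and -2.44 (knockout).

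Doxorubicin in prefasted mice was compared with untreated mice refed for the same 2 or 6 h, the contrast with time-matched controls. Of 32 p53 targets 3 rose over all genes: Plk2, a stress kinase, by log2 1.94 ± 0.27 (SE, higher in 4 of 4 pairs, adjusted p = 0.012), Trp53inp1 by 1.19 ± 0.24 and Sesn2, which restrains mTORC1, by 0.94 ± 0.18. Slfn4, an interferon-induced myeloid gene, rose by 3.27 ± 0.58 (adjusted p = 0.026), mostly from 6 h, with 5.45 ± 0.81 there (adjusted p = 0.057) and 1.09 ± 0.81 at 2 h (adjusted p = 0.65). Genes lower than in refed untreated mice included Fasn, the fatty acid synthase, at -1.68 ± 0.35, the sterol enzyme Fdft1 at -1.14 ± 0.21, Hyou1 at -0.88 ± 0.12 and Hsp90aa1 at -0.74 ± 0.15.

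Here 45 genes rose and 30 fell. Of 32 p53 target genes 3 rose over all genes and 8 adjusted over the list alone (camera, adjusted p = 7.1e-07; adjusted p = 0.10 with an estimated correlation). Cholesterol synthesis genes counted 5 fallen of 24 and 13 adjusted over the list alone (camera, adjusted p = 1e-09; adjusted p = 0.10 with an estimated correlation). Unfolded protein response genes counted 2 fallen of 19 and 12 adjusted over the list alone (camera, adjusted p = 1.2e-09; adjusted p = 0.10 with an estimated correlation). The count was 1 (Nfkbiz) without the 4 libraries with the conflicting title, which hold both wild-type libraries treated here, 3 (Rsrp1, Slfn4 and Srsf5) without the 3 lacking Y-linked reads and 258 without the 2 with pancreatic transcripts. Leaving out 1 library gave 3 (wild-type untreated 2 h: Chd3, Hyou1 and Plk2), 300 (wild-type untreated 6 h), 0 (knockout untreated 2 h), 4 (wild-type doxorubicin 2 h: Dqx1, Hyou1, Plk2 and Ugt2a3) and 14 genes (wild-type doxorubicin 6 h), and 41, 32, 40 and 32 without the ad libitum doxorubicin libraries at 12 and 24 h of the wild type and then of the knockout.

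The central comparison asked whether fasting before doxorubicin changed the response, with 7 pairs of libraries matched on genotype and time. In the 4 wild-type pairs the prefasted library has the conflicting title. If that title were right, those pairs would compare untreated with treated mice. In the 3 knockout pairs alone limma called 0 genes, with 449 at an unadjusted p under 0.05. No gene passed in limma (0 genes, 766 at an unadjusted p under 0.05 where chance gives 597); edgeR called 0 and DESeq2 21. H2-Q10, a class I histocompatibility gene named here after its values were seen, fell by 3.47 ± 0.56 on the log2 scale with fasting (adjusted p = 0.0099). In prefasted doxorubicin libraries H2-Q10 stood at 15.3 ± 1.83 normalized reads at 2 h and 51.7 ± 5.66 at 6 h (SD, n = 2), against 274 (1 library) and 494 ± 62.5 in ad libitum ones. Its log2 difference over the 7 pairs was -2.14 ± 0.38 (SE, lower in 7 of 7 pairs) and missed the threshold (adjusted p = 0.35), while in the 2 and 6 h pairs alone it fell by 3.55 (adjusted p = 0.00021). Paneth cell genes with lower values in 7 of 7 pairs that missed the threshold were Itln1 (-0.75 ± 0.13, adjusted p = 0.31), Mptx2 (-1.25 ± 0.25, adjusted p = 0.55) and Defa17 (-1.54 ± 0.34, adjusted p = 0.62). Olfm4 was at 0.54 ± 0.24 (higher in 6 of 7 pairs, adjusted p = 0.75) and Usp18, an interferon-induced gene, at -0.40 ± 0.12 (lower in 7 of 7 pairs, adjusted p = 0.75).

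As lists, Paneth cell markers had 0 of 17 passing over all genes and 8 lower adjusted over the list alone (camera, adjusted p = 1.4e-08; adjusted p = 0.31 with an estimated correlation). The G2/M list had 0 of 26 by either count, with a median of -0.50 (camera, adjusted p = 1.4e-06; adjusted p = 0.31 with an estimated correlation). Fat tissue markers, a list that holds Car3, had 0 of 9 over all genes and 3 lower adjusted over the list alone, with a median of -1.88 (camera, adjusted p = 1.5e-05; adjusted p = 0.37 with an estimated correlation), so crypt share and fat in the tissue piece may both differ here. The cholesterol synthesis genes had 0 of 24 and 3 lower adjusted over the list alone (camera, adjusted p = 8.2e-07; adjusted p = 0.31 with an estimated correlation). Among p53 target genes it was 0 of 32 by either count, over all genes or adjusted over the list alone (camera, adjusted p = 5.3e-05 with a median of -0.22; adjusted p = 0.31 with an estimated correlation). The count was 2 (Car3 and Scd1) in the wild-type pairs alone and also without either knockout library at 12 h of doxorubicin, and 2 (H2-Q10 and Rgn) in the fit of all libraries. At single times, limma called 1 gene at 6 h (Hsd17b6), and 0 at 12 h and at 24 h (421 and 329 at an unadjusted p under 0.05). There edgeR called 0 at each time, and DESeq2 84 at 6 h, 2 at 12 h (Apol10a and Cela3b, named after their values were seen) and 0 at 24 h. No count is given for 2 h, where the ad libitum arm is 1 library, without a knockout partner, that stands at 3.58 for fat tissue markers on the log2 scale relative to the mean of all libraries.

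The prefast effect under doxorubicin was further split by genotype and by time. No gene passed between knockout and wild-type pairs (limma 0, with 225 at an unadjusted p under 0.05 where chance gives 597, edgeR 0, DESeq2 0). Every wild-type prefasted library in this test has the conflicting title and no knockout library does. A difference by genotype, or its absence, therefore cannot be told apart from an effect of a wrong drug label. The conflicting titles bear on the split by time as well, since both time groups hold wild-type pairs. Between the later times (12 and 24 h) and the earlier ones limma called 0 genes (671 at an unadjusted p under 0.05), edgeR 2 (H2-Q10 and Ugt2b5) and DESeq2 23. Leaving out either wild-type library at 6 h of doxorubicin gave 1 gene, Apol10a, and leaving out either knockout library at 12 h gave 1, Rab30. The response to doxorubicin at 6 h was also compared between prefasted and ad libitum mice, each against its own untreated libraries. The untreated libraries were refed for 6 h in the former and taken at 0 h in the latter, so this test mixes feeding with the time of the control. In it limma called 0 genes (1002 at an unadjusted p under 0.05), edgeR 0 and DESeq2 46. The stress pseudokinase Trib3 had a log2 difference of -2.10 ± 0.47 in that test (adjusted p = 0.24) and Olfm4 one of 3.08 ± 0.89 (adjusted p = 0.39). Its count was 3 (Bbox1, Slc13a2 and Slc5a12) without the wild-type ad libitum untreated library, 17 and 7 without the wild-type or knockout untreated library refed for 6 h, 1 (Slc16a11) without the knockout prefasted library at 6 h of doxorubicin, and 13 without the 2 libraries with pancreatic transcripts.

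Across the 11939 genes, which are not independent replicates, the prefast effect under doxorubicin correlated weakly with the difference between untreated refed and ad libitum libraries (Pearson r = 0.11, Spearman rho = 0.18). Of the 64 ways of exchanging the feeding labels within the 7 pairs, 27, the real one among them, gave an r as large in absolute size. The highest other absolute value was 0.29. For the pairs at 2 and 6 h r was 0.21 and rho 0.28, and for those at 12 and 24 h r was -0.06 and rho -0.05.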

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

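The tests of lists between groups were planned, while the tests of explanations in this part and the criterion of at least 4 list members behind a reported difference were chosen after the results were seen; among the splits of the samples, those for the knockout and for doxorubicin in prefasted mice were planned before.

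The level of the MHC class II list was higher in the knockout library in 11 of 11 pairs (mean log2 difference 1.84 ± 0.34, SE), with 6 of 9 genes risen over all genes and 7 adjusted over the list alone (camera, adjusted p = 7.3e-19; adjusted p = 0.10 with an estimated correlation, so the list call is lost there). More B cells in the tissue pieces would have to raise B cell markers by about as much, but their median difference was -0.12 (mean level -0.26 ± 0.70, SE, 11 pairs) and their level was lower in the knockout in 7 pairs. That argues against B cells in those 7 pairs, though only 4 of the 11 listed markers were tested and the pairs ranged from -3.13 to 4.99. Macrophage markers were lower in 6 pairs and higher in 5, which weighs neither way. T cell markers were higher in 10 pairs (mean log2 difference 0.38 ± 0.12, SE), so immune cell content may differ. Of the 6 risen MHC class II genes, 5 lie close together on chromosome 17 (34119693 to 34316674) and Cd74 lies on chromosome 18. Their place on 1 chromosome follows from the choice of list. It therefore cannot tell whether a segment there differs between the mice, which stays open for those 5. The risen interferon-stimulated genes lie on chromosomes 2, 3, 4, 5, 11 and 16. Without the 3 libraries lacking Y-linked reads the MHC class II median was 2.15, with Cd74 at 2.97 (adjusted p = 0.0021) and higher in 8 of 8 pairs, so those libraries are not the whole cause. Loss of Ddit4 may raise these genes in resident cells, as a hypothesis from these data, and separate housing, flora or another strain background of the knockout mice stay open, since no label describes them.

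Of 11 clock genes of the Nr1d1 phase, 8, 8 and 5 rose over all genes at 6, 12 and 24 h of doxorubicin against the shared ad libitum libraries taken at 0 h (10, 8 and 7 adjusted over the list alone), and the list calls of camera were lost with an estimated correlation (adjusted p = 0.093, 0.25 and 0.27). Nr1d1 itself passed at none of these times. Its log2 changes were 1.16 ± 0.45, -0.77 ± 0.45 and 0.84 ± 0.45 (limma, adjusted p = 0.23, 0.31 and 0.34). Against the same ad libitum libraries, untreated mice had list medians of 1.06 (fasted) and 1.35 (refed for 2 h), and refed for 6 h a median as large as that of the drug at 24 h, so a difference in this direction is present without the drug. The hour of harvest could account for it, but hours are not given, and the median of 1.69 at 24 h does not decide it, since the drug may move these genes too. Doxorubicin itself could also contribute, with a median of 0.94 against untreated libraries refed for the same time (0.78 at 2 h alone, and 0.48 at 6 h alone against 2.61 at 6 h in ad libitum mice), where 1 of 11 genes rose over all genes and 5 adjusted over the list alone (camera, adjusted p = 5.7e-05; adjusted p = 0.29 with an estimated correlation). The hour of harvest and the drug cannot be told apart, because the ad libitum controls were taken at 0 h alone.

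At 12 h of doxorubicin in ad libitum mice Olfm4 was lower, as were 7 of 26 G2/M genes over all genes (16 adjusted over the list alone). Of 17 markers of Paneth cells, which sit in the crypt and do not divide, 3 were lower over all genes (10 adjusted over the list alone). With an estimated correlation both list calls of camera were lost (adjusted p = 0.41 and 0.48). Prefasted mice at 6 h of doxorubicin were compared with untreated mice refed for the same time. Medians were -0.30 for G2/M genes and 0.63 for Paneth cell markers, with Olfm4 at 0.02 ± 0.63 (SE, adjusted p = 0.99). Those controls were themselves low against ad libitum untreated mice, with medians of -1.94 for G2/M genes and -2.77 for Paneth cell markers. The contrast at 6 h therefore cannot show whether the fall is absent in prefasted mice. At 2 h of doxorubicin, prefasted against refed mice had medians of -1.50 for G2/M genes and -1.13 for Paneth cell markers, and Olfm4 was at -1.46 ± 0.63 (SE, adjusted p = 0.39). With the Paneth marker level as a covariate, the median of the G2/M list at 12 h moved from -1.94 to -0.87, so a smaller share of crypts in the tissue piece may account for much of it. Smooth muscle markers (median -2.07, 5 of 10 lower over all genes and 7 adjusted over the list alone) and 4 B cell markers (median -2.20, 0 by either count) were also lower at 12 h, so the pieces may differ in more than crypts. Olfm4 at 12 h had a log2 change of -5.76 ± 0.63 (SE) without and -4.82 ± 0.69 with the covariate (adjusted p = 0.0032), which argues against a smaller crypt share as its whole cause. At 6 h of refeeding the G2/M median moved from -1.65 to -0.82, and crypt share cannot be told apart from lower proliferation there, since the value lies at the boundary set for the test. Loss of Paneth cells to the drug itself would move the covariate as well and was not tested.

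Other results were differences between groups in the tests of a difference. In the response to doxorubicin at 6 h, prefasted minus ad libitum, the ad libitum control was taken at 0 h and the prefasted one after 6 h of refeeding, so feeding and the time of the control are mixed in every value. The median log2 difference was 0.83 for intestinal stem cell markers (5 of 18 adjusted over the list alone; camera, adjusted p = 5e-05; adjusted p = 0.38 with an estimated correlation), -0.70 for cholesterol synthesis genes (6 of 24; camera, adjusted p = 1.5e-09; adjusted p = 0.21 with an estimated correlation), -2.11 for clock genes of the Nr1d1 phase (8 of 11; camera, adjusted p = 7.7e-10; adjusted p = 0.21 with an estimated correlation) and -2.24 for MHC class II genes (6 of 9; camera, adjusted p = 8.3e-06; adjusted p = 0.47 with an estimated correlation). Medians of 1.53 for Paneth cell markers (0 of 17 by either count, over all genes or adjusted over the list alone), 1.26 for G2/M genes (1 of 26 adjusted over the list alone) and 1.38 for 4 B cell markers (0 by either count) lay above that of the stem cell markers, so a larger crypt share stays open for the latter. For the prefast effect at 12 and 24 h minus that at 2 and 6 h, NRF2 target genes had a median of 0.31 (4 of 12 adjusted over the list alone; camera, adjusted p = 0.0038; adjusted p = 0.67 with an estimated correlation). No member of these lists passed over all genes.

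Labels were also exchanged between libraries to see how many genes such splits call. For the knockout, 1 of 100 splits, the real one, gave as many genes (69, with 1 as the highest other), so chance is excluded at this share. For doxorubicin in prefasted mice there are 8 splits, too few for a share under 0.05, with 75 genes in the real one and 18 as the highest other. Where the real count is 0 every split reaches it, which fixes the outcome: 64 of 64 for the prefast effect (highest other 3), 35 of 35 for its difference by genotype (highest other 1), 35 of 35 for that by time (highest other 1) and 100 of 100 for genotype by drug (highest other 4).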

How the results depend on the processing

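The alternatives without the 3 libraries lacking Y-linked reads, without the 2 with pancreatic transcripts and with the Paneth marker level were chosen after seeing the data, and the others were planned. Of 201 results for named genes, 0 reversed under any alternative run. Their side of the threshold was kept by 199 with a pseudocount of 0.5, 195 with DESeq2, 181 with edgeR, 193 with quantile normalization, 165 with no filter on the mean value, 145 with array weights, 167 without the 4 libraries with conflicting titles, 114 with the Paneth covariate and 48 without the 3 lacking Y-linked reads. Those 3 are untreated, so the prefast effect and its tests by genotype and by time, within doxorubicin libraries, do not use them and did not move. For genotype by drug, leaving them out keeps only the untreated pair refed for 6 h, so the count in that setting cannot test the difference. Counts that moved by more than 1.5 times follow by setting; the cause was not tested except where libraries were left out.

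DESeq2 gave 317 genes (knockout), 148 (fasted), 146 (refed 2 h), 1395 (refed 6 h), 500 and 860 (ad libitum doxorubicin at 6 and 24 h), 383 (prefasted doxorubicin), 21 (prefast effect), 23 (by time), 46 (drug response at 6 h by feeding) and 7 (genotype by drug). Array weights gave 62 (fasted), 103 (refed 2 h), 2 (refed 6 h), 609, 2277 and 1537 (ad libitum doxorubicin at 6, 12 and 24 h), 4 (prefasted doxorubicin), 1 (prefast effect), 19 (by time) and 4 (genotype by drug). edgeR gave 19 (refed 2 h) and 2 (prefast effect by time), a pseudocount of 10 gave 2 (by time), quantile normalization 57 (refed 2 h), and no filter 25 (fasted) and 16 (refed 2 h).

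Without the 4 libraries with conflicting titles the counts were 20 (knockout), 81 (fasted), 57 (refed 2 h), 296 and 567 (ad libitum doxorubicin at 6 and 24 h), 1 (prefasted doxorubicin) and 1 (drug response at 6 h by feeding). Without the 3 lacking Y-linked reads they were 16 (knockout), 0 (fasted), 2 (refed 2 h), 0 (refed 6 h), 5, 102 and 17 (ad libitum doxorubicin at 6, 12 and 24 h), 3 (prefasted doxorubicin) and 40 (genotype by drug). Without the 2 with pancreatic transcripts they were 12 (fasted), 3 (refed 2 h), 81 (refed 6 h), 258 (prefasted doxorubicin), 13 (drug response at 6 h by feeding) and 4 (genotype by drug). The Paneth covariate gave 26 (fasted), 7 (refed 2 h), 51 (refed 6 h), 75, 190 and 141 (ad libitum doxorubicin at 6, 12 and 24 h), 47 (prefasted doxorubicin), 1 (prefast effect), 2 (by time) and 2 (drug response at 6 h by feeding), and turned the correlation across genes from 0.11 to -0.01. The knockout count was 1 in the untreated and 12 in the doxorubicin pairs alone, and the prefast count 2 in the wild-type pairs and 2 in the fit of all libraries. Genes behind counts of 5 or fewer not named before were, with array weights, Cenpe (1 of the 2 at refed 6 h), Gtpbp2, Hyou1, Plk2 and Tnrc6a (prefasted doxorubicin), Pmp22 (prefast effect) and the 4 Y-linked genes (genotype by drug, also without the 2 with pancreatic transcripts). With the Paneth covariate they were Pmp22 (prefast effect), Apol10a and Nt5e (by time) and Ypel2 (1 of the 2 for the drug response at 6 h by feeding), and otherwise H2-Q10 and Ugt2b5 (pseudocount of 10) and Nfkbiz (drug response at 6 h by feeding, without conflicting titles).

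Leaving out 1 library at a time gave 39 to 69 genes (knockout), 3 to 48 (fasted), 3 to 38 (refed 2 h), 1 to 1061 (refed 6 h), 6 to 219, 145 to 1303 and 8 to 509 (ad libitum doxorubicin at 6, 12 and 24 h), 0 to 300 (prefasted doxorubicin), 0 to 2 (prefast effect), 0 to 0 (by genotype), 0 to 1 (by time), 0 to 17 (drug response at 6 h by feeding) and 0 to 4 (genotype by drug), and a correlation of 0.03 to 0.16. The lone library left in a condition is assumed to vary like the others. Of the lists passing camera with the preset correlation, the number passing with an estimated one fell from 14 to 0 (knockout), 20 to 0 (fasted), 18 to 4 (refed 2 h), 15 to 0 (refed 6 h), 21, 18 and 23 to 0 (ad libitum doxorubicin at 6, 12 and 24 h), 20 to 0 (prefasted doxorubicin), 17 to 0 (prefast effect), 13 to 0 (by genotype), 12 to 0 (by time), 20 to 0 (drug response at 6 h by feeding) and 10 to 0 (genotype by drug). With fry the numbers were 4 (knockout), 1 (fasted), 5 (refed 2 h), 12 (refed 6 h), 4, 11 and 11 (ad libitum doxorubicin at 6, 12 and 24 h), 5 (prefasted doxorubicin) and 0 for the prefast effect and each test of a difference. Depth limits genes near the filter, since 1 read stood for up to 1.67 normalized reads.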

Other observations

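The lists in this part were fixed beforehand, and which of them to describe was chosen after their results were seen.

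At 24 h of doxorubicin in ad libitum mice, Slc40a1, the iron exporter ferroportin, fell from 3130 ± 2740 to 106 ± 67.8 normalized reads (SD, n = 2 per condition; log2 -4.68 ± 0.80, SE, adjusted p = 0.0057), and Cybrd1, a ferric reductase of the brush border, from 609 ± 672 to 7.69 ± 2.90 (log2 -5.50 ± 1.23, adjusted p = 0.026). Of the 9 proximal intestine position markers, which hold both genes and Dmbt1 (log2 -2.21 ± 0.48), 3 fell over all genes and 4 adjusted over the list alone (camera, adjusted p = 0.00049; adjusted p = 0.27 with an estimated correlation). The ad libitum untreated libraries were far apart for both, with Slc40a1 at 1190 (wild type) and 5070 (knockout) and Cybrd1 at 134 and 1080. Among 16 hypoxia genes at 24 h, 2 rose and 5 fell over all genes, and 2 and 7 adjusted over the list alone (camera, adjusted p = 0.032; adjusted p = 0.42 with an estimated correlation).

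Antimicrobial and IL-22-responsive genes in the knockout had 0 of 13 passing over all genes, and 7 higher and 1 lower adjusted over the list alone (limma; camera, adjusted p = 0.0013; adjusted p = 0.28 with an estimated correlation). Of 3 mast cell markers 1 rose over all genes and 2 adjusted over the list alone (camera, adjusted p = 0.0028; adjusted p = 0.10 with an estimated correlation). The level of pancreatic acinar markers stood at 9.13 on the log2 scale relative to the mean of all libraries in the wild-type library refed for 6 h without drug and at 7.71 in the fasted knockout library. In the wild-type ad libitum library at 2 h of doxorubicin, which has no knockout partner here, fat tissue markers stood at 3.58.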
